A study of Homo sapiens with 33 samples.

How the data were processed

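Gene expression was measured on Affymetrix human transcriptome arrays in MCF-7 cells, an estrogen receptor-positive human breast cancer line. The cells were kept without steroids for 24 h, in medium with charcoal-stripped serum, and then exposed for 48 h to the control, to 1 of 3 doses of estradiol (E2) or to 1 of 7 bisphenols. The labels give 11 groups with 3 replicates each, 33 arrays in all, and every array was placed in its group from its label. Per the labels, RNA was amplified to cDNA with a whole-transcriptome kit for small inputs and labelled with biotin before hybridization.

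The authors made the deposited values with RMA (background correction, quantile normalization and probe set summary) in Affymetrix Expression Console, and the deposited unit is log2. The versions, the probe set level and the genome build are not stated, so no coordinates are given. The table held 70523 probe sets. A single gene symbol was listed for 23781 of them and several symbols for 1543, while 45199 had none listed. Tests were run on 22465 genes, each read by its brightest probe set with a single symbol, which was a choice for the 479 genes with more than 1 probe set. Symbols were compared with a current human gene table, where 21497 were found with an Entrez identifier and 0 were changed. No total count exists for an array, so the number of arrays limits the precision. The 23 background probe sets had means from 1.93 to 8.49 and the median of the gene means was 5.83.

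Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a single fit over all 33 arrays without a block. P-values were adjusted by Benjamini-Hochberg over the 22465 genes within each comparison, and a gene passed at an adjusted p under 0.05. Each treatment was compared with control, each bisphenol with E2 at 1 nM, each E2 dose with the dose below it, each other bisphenol with BPA, and BPAP with BPF, the latter because both were used at 1000 nM. A moderated F test asked which genes differed among the groups. Intervals are 95% confidence intervals of the log2 difference from the same fit. The 19 gene lists were written from general knowledge and not chosen on these samples. They were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 19 lists within a comparison. Beside it stand camera with an estimated correlation and fry. An estrogen score was taken as the mean log2 value of the 42 measured members of the estrogen-induced list in each array, and compared between groups by exact two-sided permutation tests, whose smallest possible p with 3 against 3 arrays is 0.1. Fold changes of each bisphenol were correlated with those of E2 at 1 nM across genes, beside values simulated for unchanged groups that share the same control arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

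The genes named follow a rule written before the data were examined, as were the comparisons, lists and most of the other settings. Among genes that passed and whose arrays did not overlap between the groups, it takes the 10 largest rises and 10 largest falls for E2 at 1 nM against control, and the 5 largest of each for every other comparison. It adds up to 4 members of each list with the largest change, and in every comparison TFF1, GREB1, PGR, PDZK1, CXCL12, ESR1, CCND1, MYC, MKI67, CYP1A1 and CCNG2. Uncharacterized loci, pseudogenes, small RNAs, histones, and olfactory receptor, HLA, immunoglobulin, T cell receptor and cancer-testis family genes are skipped. Genes named outside the rule are said to be.

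The groups share replicate numbers, and the labels say that triplicates came from independent experiments without saying what a number marks. Deviations from the group means correlated at a mean of 0.308 between arrays of different groups with the same number and at -0.153 between those with different numbers, and 33 of 33 arrays lay closest to their own number. In 20 of the 26 comparisons all 3 pairs correlated above 0.1, so for these the numbers were taken to pair the arrays and the fit with the replicate number as a block is given beside a result that it changes. The comparisons of BPA, BPAF and BPZ with control, of BPAP and BPZ with BPA, and of BPAP with BPF did not meet this.

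The procedure was tested on simulated data, in which BPA arrays with known shifts were compared with control. It found 55 of 67 genes shifted by 1.5-fold, 66 of 67 shifted by 2-fold and 66 of 66 shifted by 4-fold, with 5 false calls among 22265 unshifted genes. A shifted list was found by all 3 list tests, which called 0 of the other lists. The simulated genes varied independently and carried no effect of the replicate number. The simulation thus does not give the rate of false calls for real arrays, which deviate together by number. The alternatives tried were a filter on dim genes, all probe sets, the mean of a gene's probe sets, repeated quantile normalization, median centring, the replicate block, array weights, a fit with only the groups compared, a trended and robust spread, a minimum fold of 1.5, other list tests and scores, and leaving out each array. Leaving out a replicate number in every group, cyclic loess, and weights from limma's gene-by-gene method were added after the data were seen. That method replaced the planned default weights, which stopped before converging, and was chosen after both sets of counts were seen. Probe sets with several symbols or none were left out of the gene tests, as they cannot be given to a single gene.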

Results

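The arrays recorded the transcriptome of MCF-7 cells after 48 h of exposure in 11 groups of 3 arrays. These were a control, estradiol (E2, the main natural estrogen) at 0.01, 0.1 and 1 nM, and 7 bisphenols, phenolic compounds used in plastics and resins. BPA was given at 400 nM, BPAF at 80 nM, BPAP at 1000 nM, BPB at 300 nM, BPF at 1000 nM, BPS at 1500 nM and BPZ at 400 nM. The log2 values had a minimum of 1.13, array medians ran from 4.94 to 5.10, and correlations between any pair of arrays ran from 0.983 to 0.997. All 13 luminal epithelial markers lay above the median gene, with a median level of 8.98, while 2 of 11 basal and mesenchymal markers and 2 of 14 stromal and blood cell markers did, with median levels of 5.26 and 4.05. Probe sets differ in how strongly they bind, so these levels do not compare amounts between genes or establish which cells were present.

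The comparison of E2 at 1 nM with control asked how these cells respond to estrogen itself. MGP, which encodes an inhibitor of calcification, rose 9.05-fold, from 4.79 ± 0.37 to 7.97 ± 0.07 (log2, mean ± SD, n = 3 each, adjusted p = 2.15e-08). The progesterone receptor gene PGR rose 7.14-fold, from 4.75 ± 0.43 to 7.59 ± 0.32 (adjusted p = 4.01e-06). GREB1, a cofactor of the estrogen receptor, rose 6.52-fold, from 7.24 ± 0.46 to 9.94 ± 0.09 (adjusted p = 1.97e-09). MYBL1, a transcription factor of the MYB family, rose 5.50-fold, from 4.86 ± 0.14 to 7.32 ± 0.08 (adjusted p = 1.41e-12), and the neuropeptide Y receptor gene NPY1R 5.36-fold (adjusted p = 1.19e-08). TFF1, a secreted trefoil peptide, rose 2.30-fold, from 11.54 ± 0.37 to 12.74 ± 0.14 (adjusted p = 7.58e-06). Further large rises were those of ART4 (3.67-fold), PKIB (3.50-fold), MYB (3.05-fold) and SYTL4 (2.80-fold). EPAS1, a hypoxia-inducible transcription factor, fell by 1.83 on the log2 scale, from 7.74 ± 0.35 to 5.91 ± 0.21 (adjusted p = 3.18e-08). The lipase gene LIPH fell by 1.80 (adjusted p = 3.93e-10) and the transcription factor gene SALL4 by 1.42 (adjusted p = 1.09e-10). GABBR2, PSCA, SAT1 and S1PR3 had log2 changes of -1.88, -1.68, -1.60 and -1.54.

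Some of these sizes rest on low levels. In control MGP, PGR, MYBL1, NPY1R, ART4, PKIB, ADAMTS9 and CXCL12 (4.79, 4.75, 4.86, 5.20, 3.79, 5.57, 4.87 and 4.59), and in E2 at 1 nM LIPH, GABBR2, PRICKLE2-AS3 and RND1 (4.62, 5.18, 5.33 and 5.62), lay under the median gene, 5.83, and within the means of the background probe sets, 1.93 to 8.49. Signal above background was not shown there, so these folds and log2 differences are not exact. The same limit holds in every comparison below for these genes, for AGR3 and MSMB (2.84 and 5.30 in control), for HCAR3 in BPF (5.44) and for any other gene with a group mean under 5.83. Levels from 5.83 to 8.49 lie above the median gene but still within the background means. Among these are GREB1 in control, EPAS1 with E2 at 1 nM and KRT13 in every array, so signal above background was not shown there either.

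Of the 22465 genes, 686 were higher and 565 lower in E2 at 1 nM than in control, and 394 of these 1251 changed by at least 1.5-fold. With the replicate number as a block, 1321 genes were higher and 1209 lower, 2530 in all. The larger direction depended on the processing: 475 were higher and 586 lower with arrays centred on their medians, 652 and 656 when quantile normalized again, and 750 and 794 over all probe sets. The count was 802 without E2 1 nM replicate 1, 682 without E2 1 nM replicate 2 and 741 without control replicate 3.

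Proliferation genes rose together with the estrogen targets. Of the 42 measured estrogen-induced genes 25 rose and none fell (30 rose when adjusted over the list alone, camera adjusted p = 4.35e-35), and of the 18 estrogen-repressed genes 9 fell (10 adjusted over the list alone, adjusted p = 1.71e-16), among them TP53INP1 and IL1R1, with log2 changes of -1.04 each. Of 40 genes of G1/S and DNA replication 33 rose (38 adjusted over the list alone, adjusted p = 1.91e-34), including DTL by 1.12, RRM2 by 0.83 and MCM10 by 0.78. Of 37 mitosis genes 33 rose (36 adjusted over the list alone, adjusted p = 5.15e-40), including DLGAP5 by 0.88 and PTTG1 by 0.82. Of 22 genes of ribosome biogenesis and MYC targets 10 rose (18 adjusted over the list alone, adjusted p = 5.99e-15), including ODC1, the first enzyme of polyamine synthesis, by 0.74, NOLC1 by 0.47 and FBL, a nucleolar methyltransferase gene, by 0.43. These 5 lists kept their calls with an estimated correlation (adjusted p from 2.24e-07 to 0.00737). The proliferation marker MKI67 rose by 0.69 (adjusted p = 0.000723) and the chemokine gene CXCL12 by 0.70 (adjusted p = 0.000816).

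The other lists moved less. Of 32 cytosolic ribosomal protein genes 0 passed, with a median change of 0.11, and the list was called higher (adjusted p = 0.000129, but adjusted p = 0.531 with an estimated correlation). Cholesterol biosynthesis and uptake was called higher with 1 of 19 members passing, DHCR7 at 0.45 (2 adjusted over the list alone, adjusted p = 0.000874, but adjusted p = 0.531 with an estimated correlation). The p53 targets were called lower with 1 of 17 passing, TP53INP1 (adjusted p = 0.0189, but adjusted p = 0.373 with an estimated correlation), and interferon-stimulated genes were called lower with 1 of 22 passing, OAS1 at -0.55 (adjusted p = 0.0058, but adjusted p = 0.531 with an estimated correlation). Single arrays ended these calls: cholesterol had an adjusted p of 0.0558 without control replicate 3, p53 targets 0.113 without control replicate 2 and interferon 0.152 without control replicate 1. The adjusted p of DHCR7 was 0.0638 and 0.0669 without E2 1 nM replicates 1 and 2 and 0.139 without control replicate 3, and that of OAS1 was 0.106 and 0.086 without E2 1 nM replicates 1 and 2 and 0.111 and 0.13 without control replicates 1 and 2.

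Lists that were not called still held genes that passed. Among the nuclear receptors PGR and GPER1, a membrane estrogen receptor gene (0.84), rose while AHR, the dioxin receptor gene, had a change of -0.69 (2 higher and 3 lower of 19, adjusted p = 0.962, with a median of 0.01, a mean of 0.11 and a test pointing lower). In the AHR battery ALDH1A3, a retinoic acid-forming enzyme gene, had a change of -1.27 and TIPARP rose by 0.52 (7 measured, adjusted p = 0.247, with the replicate block 0.00383). In the list of cell cycle inhibitors and quiescence YPEL3 had a change of -0.72 and GAS2L3 rose by 0.74 (1 higher and 2 lower of 19, adjusted p = 0.286, with the replicate block 0.0233). Among luminal markers TFAP2C rose by 0.50 and ELF3 had a change of -0.77 (1 higher and 2 lower of 13, adjusted p = 0.286). The hypoxia and glycolysis list had 1 gene higher and 3 lower of 20, among them EGLN3 at -0.62 (adjusted p = 0.962, with a median of 0.09 and a mean of -0.01). The remaining lists had adjusted p-values of 0.247 for NRF2 oxidative stress (1 lower of 17), 0.401 for the PXR and CAR battery (0 of 9), 0.962 for the unfolded protein and integrated stress response (3 higher and 1 lower of 21), 0.401 for basal and mesenchymal markers (1 higher of 11) and 0.962 for stromal and blood cell markers (0 of 14).

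Some genes the naming rule takes did not pass or depended on single arrays. ESR1, the estrogen receptor gene, differed by -0.06 (adjusted p = 0.843). PDZK1 differed by 0.65 (adjusted p = 0.385, with the replicate block 0.00245), CCND1 by 0.29 (0.0879, with the block 0.00743), MYC by 0.30 (0.554, with the block 0.0469) and CYP1A1 by -1.02 (0.433, with the block 0.000144). ADAMTS9 rose by 1.58 (adjusted p = 0.00859, but 0.0508 without E2 1 nM replicate 1 and 0.0779 without E2 1 nM replicate 2). PRICKLE2-AS3 had a change of -2.16 (adjusted p = 0.017, but 0.112 without E2 1 nM replicate 1, 0.0912 without E2 1 nM replicate 2, 0.0663 without control replicate 2 and 0.0831 without control replicate 3). RND1 had a change of -1.55 (adjusted p = 0.00778, but 0.0823 without control replicate 3) and ACAA2 of -1.54 (adjusted p = 0.00542, but 0.0544 without E2 1 nM replicate 2). CCNG2, a cyclin gene linked to arrest, had a change of -0.47 (adjusted p = 0.00621, but 0.0646 without E2 1 nM replicate 2 and 0.0731 without control replicate 3).

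The lower E2 doses asked where the response begins and levels off. At 0.01 nM GREB1 rose 3.22-fold (log2 1.69, interval 1.26 to 2.12, n = 3, adjusted p = 0.000148), the secreted glycoprotein gene STC1 2.49-fold (adjusted p = 0.00111), and LIPH fell by 0.84 (adjusted p = 0.00111). In all, 28 genes were higher and 32 lower than in control, and with the replicate number as a block 238 and 225, 463 in all. The balance also turned with only the brighter genes (36 and 23) and over all probe sets (32 and 23). Of the 60 genes 35 changed at least 1.5-fold. PGR rose 3.40-fold and TFF1 by 0.79, calls that ended without single arrays: the adjusted p of PGR was 0.125 and 0.0732 without E2 0.01 nM replicates 1 and 2 and 0.139 and 0.103 without control replicates 2 and 3, and that of TFF1 0.103 and 0.0604 without E2 0.01 nM replicates 2 and 3 and 0.167 without control replicate 3. Of the estrogen-induced genes 7 rose (21 adjusted over the list alone), of the repressed 2 fell (3 adjusted over the list alone) and of ribosome biogenesis 2 rose (8 adjusted over the list alone). Of the G1/S and mitosis genes 0 passed (26 and 22 adjusted over the list alone). All 5 lists were called in the directions of 1 nM, and kept with an estimated correlation (largest adjusted p = 0.0327). Ribosomal proteins were called higher (adjusted p = 3.04e-05, but adjusted p = 0.62 with an estimated correlation) and interferon-stimulated genes lower (adjusted p = 0.00107, but adjusted p = 0.631 with an estimated correlation, 0.188 without E2 0.01 nM replicate 2 and 0.162 without control replicate 1). With the replicate block cholesterol (0.0031), the AHR battery (0.00965) and luminal markers (0.00961) were called as well. The gene count was 28 without E2 0.01 nM replicate 1 or 3, and 133, 26 and 25 without control replicates 1, 2 and 3. It was 13, 5 and 5 without replicate numbers 1, 2 and 3 in all groups, and with only the 2 groups compared in the fit 0 genes passed, so these calls depend on the variance taken from the other groups.

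At 0.1 nM, with the limit for low control levels given above for PGR, MGP, NPY1R and MYBL1, PGR rose 7.80-fold (log2 2.96, interval 2.26 to 3.67, n = 3), MGP 7.20-fold, GREB1 6.64-fold, NPY1R 5.07-fold and MYBL1 4.54-fold, while EPAS1 fell by 1.81, LIPH by 1.66 and PSCA by 1.62. TFF1 rose by 1.21 and MKI67 by 0.75 (adjusted p = 0.000268). The test called 803 genes higher and 440 lower, 1243 in all (with the replicate block 1532 and 1024, 2556 in all), of which 383 changed at least 1.5-fold. Of the estrogen-induced genes 28 rose (32 adjusted over the list alone), of the repressed 7 fell (8), of G1/S 33 rose (39), of mitosis 34 (36) and of ribosome biogenesis 12 (19), each bracket giving the count adjusted over the list alone, and each list was kept with an estimated correlation. Ribosomal proteins (adjusted p = 0.000258, but adjusted p = 0.544 with an estimated correlation, and 0.314 without E2 0.1 nM replicate 2) and cholesterol genes (adjusted p = 3.81e-05, but adjusted p = 0.518 with an estimated correlation) were called higher, and with the replicate block the AHR battery lower (0.000476). The gene count was 705 and 726 without E2 0.1 nM replicates 1 and 2, and 817 and 731 without control replicates 2 and 3.

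Between 0.01 and 0.1 nM MGP rose 3.98-fold (log2 1.99, interval 1.42 to 2.57, n = 3, adjusted p = 8e-04) and MYBL1 2.58-fold (interval 1.11 to 1.63, adjusted p = 1.08e-06), while LIPH fell by 0.82 (adjusted p = 0.00174) and RAB27B by 0.67 (adjusted p = 0.00133). This step had 19 genes higher and 16 lower (with the replicate block 199 and 149, 348 in all, and quantile normalized again 20 and 25), a count of 12 and 18 without E2 0.1 nM replicates 1 and 2 and of 21 and 11 without E2 0.01 nM replicates 1 and 2. From 0.1 to 1 nM limma called 0 genes, with and without the block, against 449 genes at an unadjusted p under 0.05 (smallest adjusted p = 0.456). GREB1 differed by -0.03 (interval -0.46 to 0.40), PGR by -0.13 (-0.84 to 0.58) and TFF1 by -0.01 (-0.32 to 0.30).

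All 7 bisphenols changed estrogen-responsive genes in the direction of E2. Called higher in all 10 treatments were 25 genes, among them GREB1, PGR, TFF1, MYB, MYBL1, MSMB, STC1 and the cell cycle ubiquitin ligase subunit gene SKP2, and called lower in all 10 were 29, among them EPAS1, LIPH, IL1R1, SALL4 and EGLN3. In E2 at 0.01 nM the adjusted p of EPAS1 was 0.00753, but 0.057 without E2 0.01 nM replicate 1 and 0.102 without control replicate 3. In all 7 bisphenols 65 genes were higher, 64 of them also with E2 at 1 nM, and 69 lower, all 69 also with E2 at 1 nM. At least 1 bisphenol raised 756 genes and lowered 437, and 0 genes were higher in a treatment and lower in another. All 10 treatments were compared with the same control arrays, so part of this agreement in direction is built in. Simulated unchanged groups that shared controls agreed in sign over all genes at a median share of 0.681 (95% between 0.481 and 0.844). The F test over the 11 groups called 355 genes (with the replicate block 1413), and 175 and 193 without control replicates 2 and 3. ESR1 passed in none of the 10 treatments, with differences from -0.06 to 0.11.

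**Figure D1:**
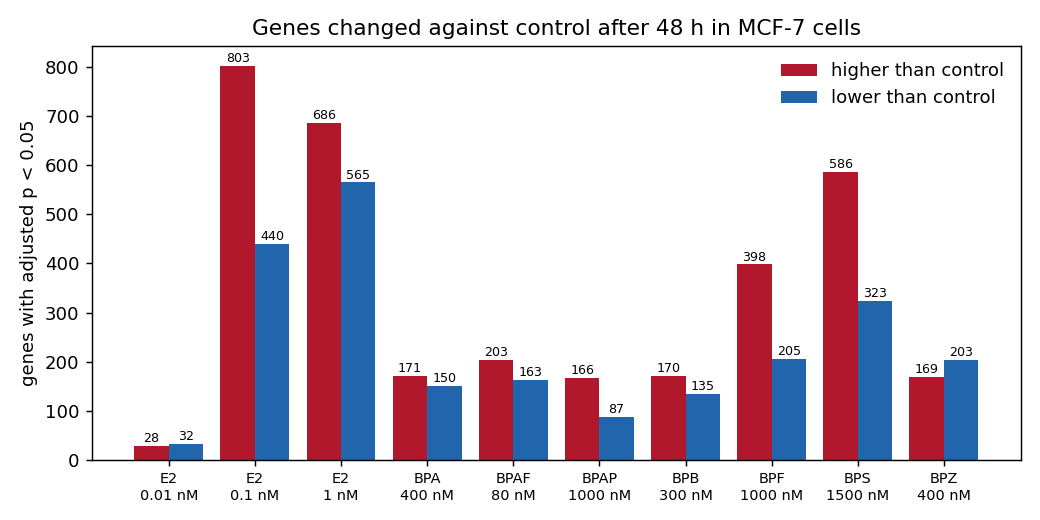
Number of genes called higher (red bars) and lower (blue bars, beside them) than control at an adjusted p under 0.05 in each of the 10 treatments, 3 arrays each. E2 at 0.1 and 1 nM gave 1243 and 1251 genes, BPS 909 and the other bisphenols 253 to 603.

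BPA, which has a pair of phenols on a carbon bridge with methyl groups, raised PGR 4.18-fold (log2 2.07, interval 1.36 to 2.77, n = 3, adjusted p = 0.00131), GREB1 3.28-fold (1.71, 1.28 to 2.14, adjusted p = 2.9e-05) and STC1 2.82-fold (adjusted p = 6.07e-05) at 400 nM. EPAS1 fell by 1.53 (adjusted p = 6.35e-06), LIPH by 1.35 (adjusted p = 4.07e-07), and TFF1 rose by 0.91 (adjusted p = 0.00132). In all, 171 genes were higher and 150 lower (median centred 106 and 154, quantile normalized again 172 and 180, over all probe sets 144 and 151, and with the replicate block 622 and 637), and 109 changed at least 1.5-fold. Among estrogen-induced genes 16 rose (24 adjusted over the list alone), of the repressed 4 fell (8), of G1/S 16 rose (36), of mitosis 9 (32) and of ribosome biogenesis 4 (15). The gene count was 131 and 173 without BPA replicates 1 and 2, and 163 and 134 without control replicates 2 and 3.

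BPAF, in which the methyl groups are trifluoromethyl, was used at 80 nM, the lowest bisphenol dose. It raised PGR 4.82-fold (log2 2.27, interval 1.56 to 2.98, n = 3), AGR3, a gene of the protein disulfide isomerase family, 3.25-fold, GREB1 and STC1 2.89-fold each and MSMB, a secreted prostate protein gene, 2.56-fold (adjusted p = 2.54e-06). EPAS1 fell by 1.29, PSCA by 1.24 and LIPH by 1.21, and TFF1 rose by 0.73 (adjusted p = 0.0106, but 0.0826 without BPAF replicate 2 and 0.126 without control replicate 3). In all, 203 genes were higher and 163 lower (median centred 145 and 158), and 128 changed at least 1.5-fold. Of the estrogen-induced genes 18 rose (22 adjusted over the list alone), of the repressed 5 fell (9), of G1/S 21 rose (37), of mitosis 10 (34) and of ribosome biogenesis 5 (15). Called genes numbered 169 and 136 without BPAF replicates 1 and 2, and 170 and 136 without control replicates 2 and 3.

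BPAP, in which a methyl is replaced by phenyl, was used at 1000 nM. It raised PGR 4.63-fold (log2 2.21, n = 3, adjusted p = 0.000596), AGR3 3.78-fold, STC1 3.06-fold, MSMB 2.82-fold (adjusted p = 9.68e-07) and GREB1 2.58-fold (adjusted p = 0.000527). EPAS1 fell by 1.21 and LIPH by 1.06. TFF1 rose by 0.62 (adjusted p = 0.0423), a call that ended with median centring (0.093) and without BPAP replicates 1, 2 and 3 (0.0687, 0.25 and 0.0685) or control replicates 2 and 3 (0.0675 and 0.366). In all, 166 genes were higher and 87 lower (with the replicate block 641 and 409, 1050 in all, and quantile normalized again 130 and 109), and 83 changed at least 1.5-fold. Among estrogen-induced genes 18 rose (28 adjusted over the list alone), of the repressed 3 fell (7), of G1/S 9 rose (31), of mitosis 6 (32) and of ribosome biogenesis 4 (11). The gene count was 130 and 138 without BPAP replicates 1 and 3, and 108 and 105 without control replicates 2 and 3.

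BPB, in which a methyl is replaced by ethyl, raised PGR 4.80-fold (log2 2.26, interval 1.56 to 2.97, n = 3), GREB1 3.30-fold, AGR3 3.25-fold, MGP 2.98-fold and STC1 2.81-fold at 300 nM. EPAS1 fell by 1.47, PSCA by 1.23, ALDH1A3 and LIPH by 1.22 each, and TFF1 rose by 0.83 (adjusted p = 0.00326). In all, 170 genes were higher and 135 lower (with the replicate block 657 and 543, 1200 in all, median centred 121 and 146, and quantile normalized again 177 and 179), and 110 changed at least 1.5-fold. Of the estrogen-induced genes 17 rose (23 adjusted over the list alone), of the repressed 4 fell (7), of G1/S 10 rose (34), of mitosis 6 (28) and of ribosome biogenesis 4 (9). Called genes numbered 168, 177 and 195 without BPB replicates 1, 2 and 3, and 169 and 144 without control replicates 2 and 3.

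BPF, with a plain methylene bridge, raised PGR 5.37-fold (log2 2.42, interval 1.72 to 3.13, n = 3), GREB1 3.99-fold, NPY1R 3.35-fold, AGR3 3.18-fold and MGP 3.02-fold at 1000 nM. EPAS1 fell by 1.47, the hydroxycarboxylic acid receptor gene HCAR3 by 1.43 and ALDH1A3 by 1.27, and TFF1 rose 2.14-fold (adjusted p = 0.000108). In all, 398 genes were higher and 205 lower, 603 together (with the replicate block 1212 and 708, 1920 in all), and 165 changed at least 1.5-fold. Among estrogen-induced genes 20 rose (27 adjusted over the list alone), of the repressed 4 fell (7), of G1/S 15 rose (36), of mitosis 19 (34) and of ribosome biogenesis 6 (15). The gene count was 231 without BPF replicate 2, and 288 and 325 without control replicates 2 and 3.

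BPS, with a sulfone bridge and the highest dose, 1500 nM, had the most called genes among the bisphenols in this fit, while with array weights the counts of BPZ, BPS and BPA were 1482, 1481 and 1418. It raised PGR 6.92-fold (log2 2.79, interval 2.08 to 3.50, n = 3, adjusted p = 1.12e-05), GREB1 5.48-fold (adjusted p = 3.89e-08), MGP 4.57-fold, NPY1R 4.02-fold and MYBL1 3.83-fold (adjusted p = 4.33e-10). GABBR2 fell by 1.66, EPAS1 by 1.65, PSCA by 1.61 and LIPH by 1.40, while TFF1 rose by 1.05 and MKI67 by 0.66 (adjusted p = 0.00149). In all, 586 genes were higher and 323 lower, 909 together (with the replicate block 1267 and 874, 2141 in all), and 289 changed at least 1.5-fold. Of the estrogen-induced genes 25 rose (29 adjusted over the list alone), of the repressed 8 fell (8), of G1/S 31 rose (38), of mitosis 32 (35) and of ribosome biogenesis 10 (19). Called genes numbered 528 and 560 without BPS replicates 1 and 2, and 546 and 527 without control replicates 2 and 3.

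BPZ, with a cyclohexylidene bridge, raised PGR 4.59-fold (log2 2.20, interval 1.49 to 2.90, n = 3), GREB1 3.50-fold, AGR3 3.34-fold and STC1 2.82-fold at 400 nM. EPAS1 fell by 1.42, LIPH by 1.33, PSCA by 1.24 and the polyamine acetyltransferase gene SAT1 by 1.13, and TFF1 rose by 0.82 (adjusted p = 0.00304). In all, 169 genes were higher and 203 lower (median centred 117 and 227, and with array weights 767 and 715), and 117 changed at least 1.5-fold. Among estrogen-induced genes 20 rose (28 adjusted over the list alone), of the repressed 4 fell (8), of G1/S 8 rose (33), of mitosis 3 (25, camera adjusted p = 3.24e-15, but adjusted p = 0.174 with an estimated correlation) and of ribosome biogenesis 5 (9). Called genes numbered 170 without BPZ replicate 1, and 233 and 163 without control replicates 2 and 3.

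Apart from mitosis in BPZ, these 5 lists were called for each bisphenol and kept with an estimated correlation, in BPZ with adjusted p = 0.0464 for G1/S and 0.0259 for ribosome biogenesis. The mean log2 value of the mitosis genes per array overlapped control in BPA, BPAP and E2 at 0.01 nM (exact permutation p = 0.2 each). It did not overlap in BPAF, BPB, BPF, BPS and BPZ (exact permutation p = 0.1 each). The bracketed member counts for the bisphenols are those adjusted over the list alone.

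The smaller list shifts of the bisphenols, with at most 1 member of a list passing, were lost with an estimated correlation. Ribosomal proteins were called higher in BPA, BPAF, BPAP, BPB, BPF and BPS (adjusted p = 0.00272, 0.00341, 0.000137, 0.00241, 1.52e-09 and 2.25e-06, but adjusted p = 0.69, 0.65, 0.679, 0.71, 0.301 and 0.498 with an estimated correlation). Cholesterol genes were called higher in BPA, BPAF, BPAP, BPB and BPS (adjusted p = 0.0284, 0.00809, 0.0388, 0.0344 and 0.000554, but adjusted p = 0.69, 0.65, 0.679, 0.71 and 0.498 with an estimated correlation). Interferon-stimulated genes were called lower in BPA, BPAF, BPAP and BPZ (adjusted p = 0.0317, 0.000336, 0.0262 and 1.62e-05, but adjusted p = 0.69, 0.534, 0.679 and 0.37 with an estimated correlation). Luminal markers were called lower in BPAF and BPZ (adjusted p = 0.0384 and 0.0136, but adjusted p = 0.336 and 0.182 with an estimated correlation), and p53 targets lower in BPZ (adjusted p = 0.0204, but adjusted p = 0.315 with an estimated correlation). With the replicate block the AHR battery was called in BPAP (0.00199), BPB (0.000898), BPF (0.00461) and BPS (0.000889), quiescence in BPB (0.0385) and BPF (0.0468), cholesterol in BPF (0.00461), and p53 targets (0.0278) and luminal markers (0.0425) in BPB. The block also added 4 lists in BPA, 1 in BPAF and 3 in BPZ, whose comparisons with control did not meet the rule for pairing. Calls added by the block are thus not particular to the bisphenols named.

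Single arrays or another scaling ended several of these smaller calls. Quantile normalized again, the adjusted p was 0.0608 for cholesterol in BPAP and 0.314 for luminal markers in BPZ, and median centred 0.0606 for luminal markers in BPAF. Without control replicate 3 the adjusted p of the cholesterol list was 0.694 in BPA, 0.495 in BPAF, 0.783 in BPAP, 0.748 in BPB and 0.111 in BPS. It was 0.0884 and 0.641 without BPA replicates 1 and 2, 0.641 without BPAF replicate 2, 0.105 and 0.252 without BPAP replicates 1 and 2, and 0.0534 and 0.695 without BPB replicates 1 and 2. Without control replicate 1 the interferon list had 0.523 in BPA, 0.0685 in BPAF and 0.52 in BPAP, and it had 0.126 and 0.134 without BPA replicates 1 and 2, 0.0654 without BPAF replicate 2 and 0.516 without BPAP replicate 2. Ribosomal proteins had 0.0742 without BPAF replicate 1, 0.263 without BPAP replicate 3, and 0.053 in BPAF and 0.0507 in BPB without control replicate 3. Luminal markers had 0.508 without BPAF replicate 3, 0.12 and 0.053 in BPAF without control replicates 1 and 3, and 0.0641 and 0.158 without BPZ replicates 1 and 3. The p53 targets in BPZ had 0.159, 0.158 and 0.138 without BPZ replicates 1 and 3 and control replicate 2.

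**Figure D2:**
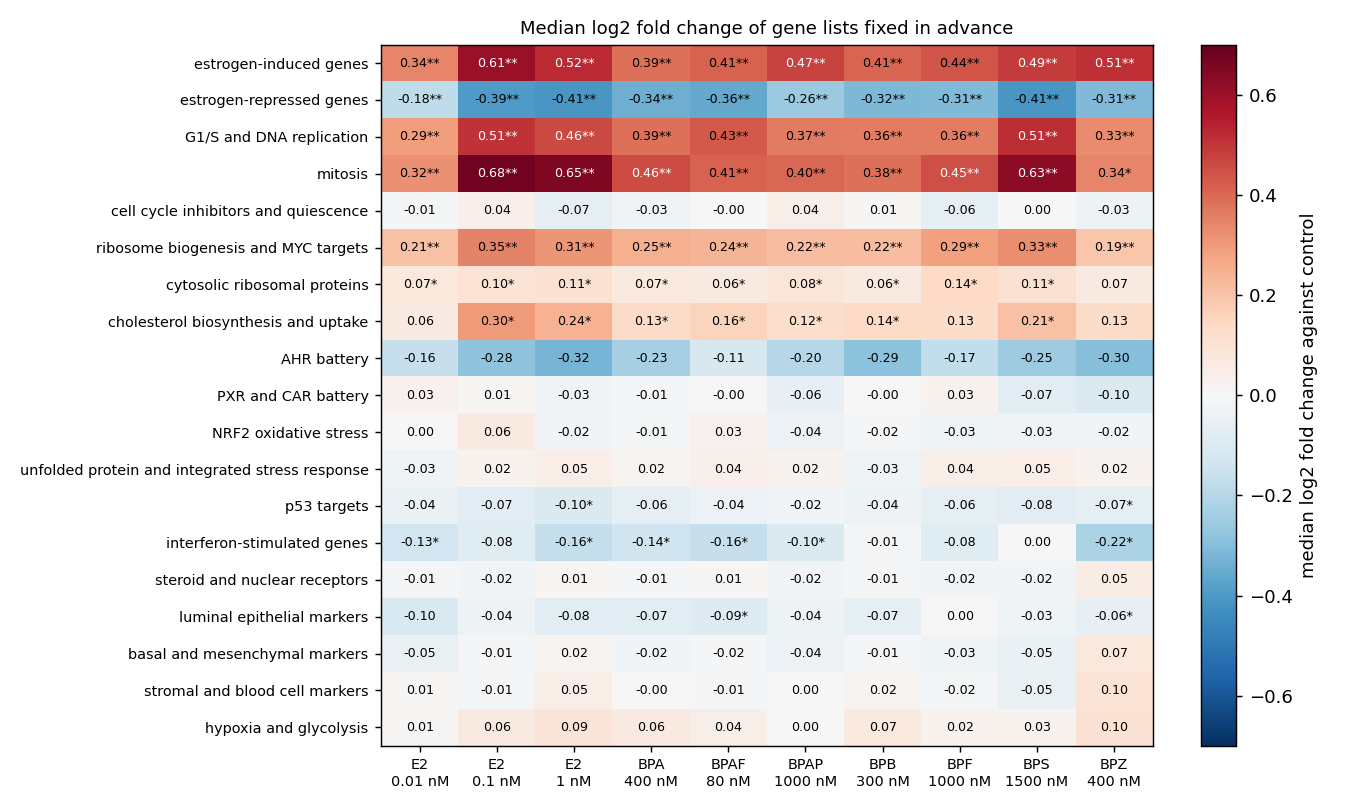
Median log2 change against control of the measured members of each of the 19 gene lists (vertical) in each of the 10 treatments (horizontal), 3 arrays per group. Stars mark lists called by 1 (*) or both (**) of camera with a preset and with an estimated correlation, and mitosis in E2 at 1 nM had a median of 0.65.

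The estrogen score, the mean log2 value of the 42 estrogen-induced genes, was 6.82 ± 0.12 in control (mean ± SD, n = 3). It was 7.26 ± 0.03, 7.64 ± 0.05 and 7.60 ± 0.05 with E2 at 0.01, 0.1 and 1 nM. For the bisphenols it was 7.36 ± 0.05 with BPA, 7.38 ± 0.03 with BPAF, 7.41 ± 0.02 with BPAP, 7.39 ± 0.01 with BPB, 7.44 ± 0.04 with BPF, 7.55 ± 0.03 with BPS and 7.43 ± 0.07 with BPZ. No treated array overlapped the control arrays, which gave an exact permutation p of 0.1 for each treatment, the smallest this design allows, and 0.144 adjusted over the 26 differences tested. Scores of BPA, BPAF, BPAP, BPB, BPF and BPZ lay below E2 at 1 nM by differences of -0.25, -0.22, -0.19, -0.21, -0.16 and -0.17 without overlap (exact permutation p = 0.1 each). BPS differed from it by -0.05 (interval -0.15 to 0.04, exact permutation p = 0.3).

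**Figure D3:**
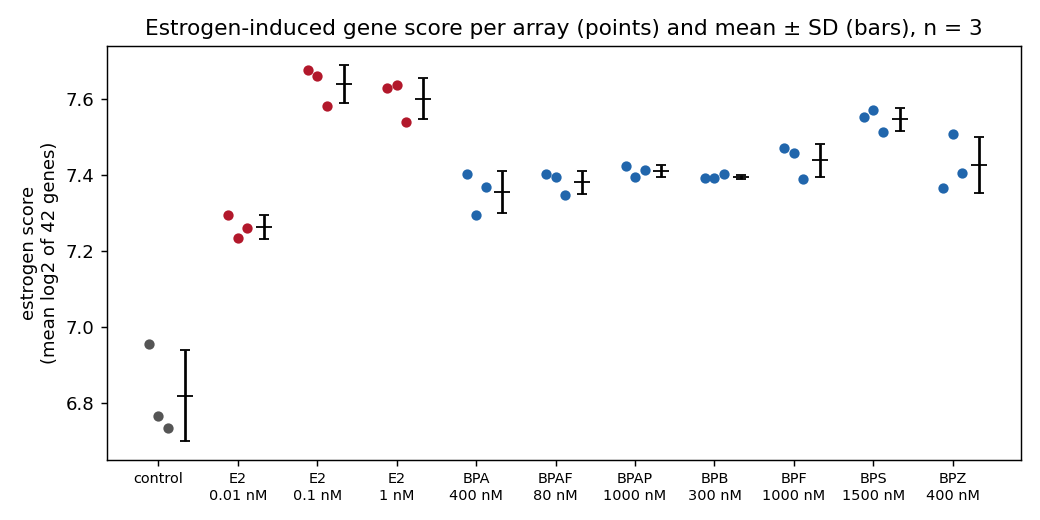
Estrogen score of each array (mean log2 value of 42 estrogen-induced genes, vertical) in the 11 groups, with the mean and SD of 3 arrays. Control lies at 6.82 and every treatment above it, from 7.26 with E2 at 0.01 nM to 7.64 with E2 at 0.1 nM.

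Across the 22465 genes, which are not independent replicates, the fold changes of each bisphenol were correlated with those of E2 at 1 nM. Pearson's r was 0.841 for BPA, 0.835 for BPAF, 0.789 for BPAP, 0.825 for BPB, 0.765 for BPF, 0.840 for BPS and 0.822 for BPZ, where simulated unchanged groups against the same controls had a median of 0.543 (95% between 0.165 and 0.813) and a maximum of 0.848. Those of BPA, BPAF, BPB, BPS and BPZ lay above the 95% range and under the maximum of the 100 simulations, and those of BPAP and BPF inside the range, so r does not tell BPAP and BPF apart from unchanged groups with shared controls. The covariances were 0.0285, 0.0285, 0.0256, 0.0279, 0.0289, 0.0336 and 0.0298 in the same order, all above the simulated maximum of 0.017 (simulated median 0.00523). Against E2 at 1 nM minus E2 at 0.01 nM, which shares no array with bisphenol minus control, r was 0.493, 0.489, 0.432, 0.477, 0.444, 0.501 and 0.534. Called in the same direction with E2 at 1 nM were 308 of the 321 genes of BPA (165 higher where independent lists would share 5.22, 143 lower where they would share 3.77), 343 of 366 for BPAF, 225 of 253 for BPAP, 288 of 305 for BPB, 468 of 603 for BPF, 739 of 909 for BPS (456 higher against 17.9, 283 lower against 8.12) and 328 of 372 for BPZ. Called in opposite directions were 0. Simulated unchanged groups shared 0, but they carried no effect, so this does not gauge how much real responses would share through the same controls. The 3 control arrays cannot be split into parts of at least 2, so part of the excess may come from the shared controls. Of the genes called with a bisphenol but not with E2 at 1 nM, 13, 23, 28, 17, 135, 170 and 44 in the same order, 0, 2, 3, 0, 0, 0 and 1 were called different from E2.

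The direct comparison with E2 at 1 nM asked where a bisphenol differed from the hormone. MYBL1 was lower in 6 bisphenols, with log2 differences of -1.46 in BPA (interval -1.72 to -1.20, n = 3, adjusted p = 2.71e-07), -1.47 in BPAF, -1.70 in BPAP (adjusted p = 9.27e-09), -1.53 in BPB, -1.14 in BPF (adjusted p = 4.67e-05) and -1.62 in BPZ. SALL4, which E2 lowered, was called higher in the same 6 bisphenols, BPAF included. It was higher by 0.72 in BPA, 0.83 in BPAP, 0.68 in BPB, 0.63 in BPF (adjusted p = 0.00245, but 0.0517 without E2 1 nM replicate 2) and 0.61 in BPZ. MGP was called lower in the same 6 bisphenols, among them by a difference of -2.24 in BPAP (adjusted p = 7.78e-05) and of -1.98 in BPAF (adjusted p = 0.00116). The neighbouring keratin genes KRT13 and KRT15 were higher in BPAP, KRT13 by 1.06 (interval 0.82 to 1.30, adjusted p = 1.16e-05) and KRT15 by 0.84 (interval 0.63 to 1.06, adjusted p = 7.78e-05). Each of these keratin genes was called higher in 3 bisphenols, BPAP among them. In all, 47 genes differed in at least 1 bisphenol.

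Against E2 at 1 nM BPA had 5 genes higher and 8 lower (with the replicate block 57 and 44, 101 in all), BPAF 8 and 11 (79 and 52), BPAP 30 and 16 (242 and 87), BPB 5 and 4 (104 and 56), BPF 5 and 2 (126 and 47) and BPZ 6 and 8 (68 and 61), the bracket giving the blocked counts, in which higher genes were the more numerous in all 6. In BPS limma called 0 genes, with and without the block, against 834 at an unadjusted p under 0.05 (smallest adjusted p = 0.582), with GREB1 differing by -0.25 (interval -0.68 to 0.18), PGR by -0.04 (-0.75 to 0.66) and TFF1 by -0.15 (-0.46 to 0.16), and with array weights it had 3. Median centred, BPA had 4 higher and 4 lower and BPB 7 and 7, and quantile normalized again BPA had 8 and 8, BPAF 10 and 10 and BPZ 13 and 8. With array weights BPAF had 102 and 77, over all probe sets BPB had 3 and 5 and BPF 4 and 4, and with only the brighter genes BPB had 10 and 10. Counts also moved with single arrays. For BPA it was 3 and 4 without BPA replicates 1 and 2, and 6 and 5 without E2 1 nM replicates 1 and 2. For BPAF it was 10, 12 and 9 without BPAF replicates 1, 2 and 3, and 9 without E2 1 nM replicate 1. For BPAP it was 26 and 27 without BPAP replicates 1 and 3, and 26 and 20 without E2 1 nM replicates 1 and 2, and for BPB 5 without BPB replicate 2. For BPF it was 63, 2 and 2 without BPF replicates 1, 2 and 3, and 3 and 1 without E2 1 nM replicates 1 and 2. For BPS it was 1 and 2 without E2 1 nM replicates 1 and 3. For BPZ it was 5 and 7 without BPZ replicates 1 and 3, and 4, 8 and 8 without E2 1 nM replicates 1, 2 and 3.

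The estrogen lists were less shifted with 6 of the bisphenols than with E2 at 1 nM. Estrogen-induced genes were called lower in BPA (adjusted p = 1.33e-14, 2 members passing, 13 adjusted over the list alone), BPAF (1.35e-11, 3 and 13), BPAP (2.48e-07, 3 and 12), BPB (6.34e-11, 1 and 11), BPF (3.1e-05, 1 and 7) and BPZ (1.37e-08, 2 and 7). Adjusted over the list alone, 0, 2, 3, 2, 1 and 2 members were higher in the same order. Estrogen-repressed genes were called higher in the same 6 (adjusted p from 2.25e-08 in BPAP to 0.000149 in BPF) with 0 of 18 members passing, 3 in BPAP and 1 in BPF adjusted over the list alone. Both lists kept these calls with an estimated correlation (largest adjusted p = 0.0341). In BPS the repressed list had an adjusted p of 0.164 (with the replicate block 0.0261). Mitosis genes were called lower in BPZ, with a median of -0.31, 0 members passing and 16 adjusted over the list alone (adjusted p = 1.5e-33, and adjusted p = 0.0252 with an estimated correlation), and ribosome biogenesis genes too (adjusted p = 1.26e-06, and adjusted p = 0.0431 with an estimated correlation).

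Other list differences from E2 at 1 nM, with 0 members passing, were lost with an estimated correlation. Mitosis genes were called lower in BPA, BPAF, BPAP, BPB and BPF (adjusted p = 2.07e-14, 1.17e-12, 2.48e-16, 1.01e-18 and 2.93e-05, but adjusted p = 0.319, 0.399, 0.23, 0.163 and 0.847 with an estimated correlation). G1/S genes were called lower in BPA, BPAP, BPB, BPF and BPZ (adjusted p = 0.000516, 5.65e-06, 1.75e-05, 0.012 and 9.49e-12, but adjusted p = 0.816, 0.566, 0.685, 0.847 and 0.171 with an estimated correlation), and in BPAF with the replicate block (0.0296). Ribosome biogenesis was called lower in BPAP and BPB (adjusted p = 0.0286 and 0.000868, but adjusted p = 0.566 and 0.263 with an estimated correlation, in BPAP 0.103 when median centred). Ribosomal proteins were called lower in BPAF and BPZ (adjusted p = 0.0396 and 0.000643, but adjusted p = 0.919 and 0.598 with an estimated correlation), and with the replicate block in BPB (0.0425). Their direction turned in BPZ when quantile normalized again (0.955), and in BPAF that setting gave 0.205 and median centring 0.133. Cholesterol genes were called lower in BPA, BPAP, BPB and BPZ (adjusted p = 0.0276, 0.0286, 0.0222 and 0.000622, but adjusted p = 0.816, 0.883, 0.765 and 0.598 with an estimated correlation), and with the block in BPAF (0.00122) and BPF (0.000953). The NRF2 list was called higher in BPAF (adjusted p = 0.026, but adjusted p = 0.919 with an estimated correlation, and 0.066 when median centred), and with the block in BPAP (0.0364), BPB (0.0077) and BPS (0.04). The p53 targets were called higher in BPAF and BPAP (adjusted p = 0.026 and 0.0381, but adjusted p = 0.493 and 0.566 with an estimated correlation, in BPAP 0.0837 when quantile normalized again), and with the block in BPS (0.0261). Interferon-stimulated genes were called higher in BPB and BPS (adjusted p = 0.000296 and 7.49e-06, but adjusted p = 0.685 and 0.756 with an estimated correlation). With the block the AHR battery was called in BPAF (0.00169) and quiescence in BPAP (0.0364).

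Most of these list differences rested on single arrays. Without BPA replicate 3 the adjusted p was 0.885 for G1/S and 0.900 for cholesterol, whose direction turned, in BPA, and without E2 1 nM replicate 2 it was 0.132 and 0.582, with 0.106 for cholesterol without E2 1 nM replicate 1. In BPAF it was 0.802 for NRF2, whose direction turned, and 0.621 for p53 without BPAF replicate 2, 0.713 for ribosomal proteins without BPAF replicate 3, 0.609 for NRF2 and 0.13 for p53 without E2 1 nM replicate 1, 0.941 for ribosomal proteins without E2 1 nM replicate 2, and 0.283 and 0.0538 for ribosomal proteins and NRF2 without E2 1 nM replicate 3. In BPAP it was 0.111 for G1/S, 0.594 for ribosome biogenesis and 0.37 for p53 without BPAP replicate 2, 0.328 for cholesterol and p53 without BPAP replicate 3, 0.0835 and 0.143 for these without E2 1 nM replicate 1, and 0.319, 0.506 and 0.0512 for ribosome biogenesis, cholesterol and p53 without E2 1 nM replicate 2. In BPB it was 0.145, 0.323 and 0.978 for G1/S, ribosome biogenesis and cholesterol without BPB replicate 3, 0.0846 for cholesterol without E2 1 nM replicate 1, and 0.0515 and 0.532 for ribosome biogenesis and cholesterol without E2 1 nM replicate 2. In BPF G1/S had 0.664, 0.139 and 0.276 without BPF replicate 3 and E2 1 nM replicates 1 and 2. In BPZ ribosomal proteins had 0.13 and 0.304 without BPZ replicate 1 and E2 1 nM replicate 2, and cholesterol 0.331 and 0.0859 without BPZ replicate 3 and E2 1 nM replicate 2. In BPS the interferon list had 0.723 without BPS replicate 3. The number of lists called was 8 and 3 without BPA replicates 2 and 3, 4 in BPB without BPB replicate 3, 7 in BPF without E2 1 nM replicate 3, and in BPS 5 without BPS replicate 1 and 2, 5 and 2 without E2 1 nM replicates 1, 2 and 3.

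BPZ and BPA, which differ in the ring or methyl groups on the bridge carbon, were both given at 400 nM and could be compared at a matched dose. GREB1 differed by 0.09 (BPZ minus BPA, interval -0.34 to 0.52, n = 3), PGR by 0.13 (-0.58 to 0.84), TFF1 by -0.09 (-0.41 to 0.22) and the estrogen score by 0.07 (-0.02 to 0.16, exact permutation p = 0.3, with the median of members -0.030). In limma 0 genes passed, against 853 at an unadjusted p under 0.05 (smallest adjusted p = 0.425). With array weights 3893 passed, so this comparison depends on how single arrays are weighted. These weights were fitted without the replicate number and gave BPA replicate 1 a weight of 4.64, beside 0.647 and 0.425 for BPA replicates 2 and 3. With the replicate number as a block 0 genes passed.

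BPAP and BPF, with a phenyl and methyl or only hydrogens on the bridge carbon, were both given at 1000 nM. KRT13, a keratin of stratified epithelia, was 1.85-fold higher in BPAP, at 7.50 ± 0.11 against 6.61 ± 0.11 (log2 difference 0.89, interval 0.65 to 1.13, n = 3, adjusted p = 0.00093), and was the only gene of 22465 that passed. GREB1 differed by -0.63 (interval -1.06 to -0.20, adjusted p = 0.948), TFF1 by -0.48 (-0.79 to -0.17, adjusted p = 0.948), PGR by -0.21 (-0.92 to 0.49) and the score by -0.03 (-0.12 to 0.06, exact permutation p = 0.4). The count was 8 without BPF replicate 1, and 0 without replicate number 1 or 3 in all groups and with only the 2 groups compared in the fit.

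At doses that differed from that of BPA, 1 gene differed in BPAP and 1 in BPS. KRT13 was 1.71-fold higher in BPAP than in BPA (log2 0.77, interval 0.54 to 1.01, n = 3, adjusted p = 0.01), a call that ended without BPAP replicate 1 (0.172), BPAP replicate 3 (0.143) or BPA replicate 2 (0.292). MYBL1 was 1.91-fold higher in BPS (log2 0.94, interval 0.67 to 1.20, adjusted p = 0.00192, but 0.0562 without BPS replicate 1 and 0.151 with the mean of its probe sets). The score of BPS exceeded that of BPA by 0.19 (interval 0.10 to 0.28, exact permutation p = 0.1). Against BPA limma called 0 genes in BPAF, BPB and BPF, with 235, 322 and 881 at an unadjusted p under 0.05, and 2 in BPF without BPF replicate 1. With array weights they had 109, 223 and 1. With only the 2 groups compared in the fit, 0 genes passed in BPAP and BPS against BPA.

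**Figure D4:**
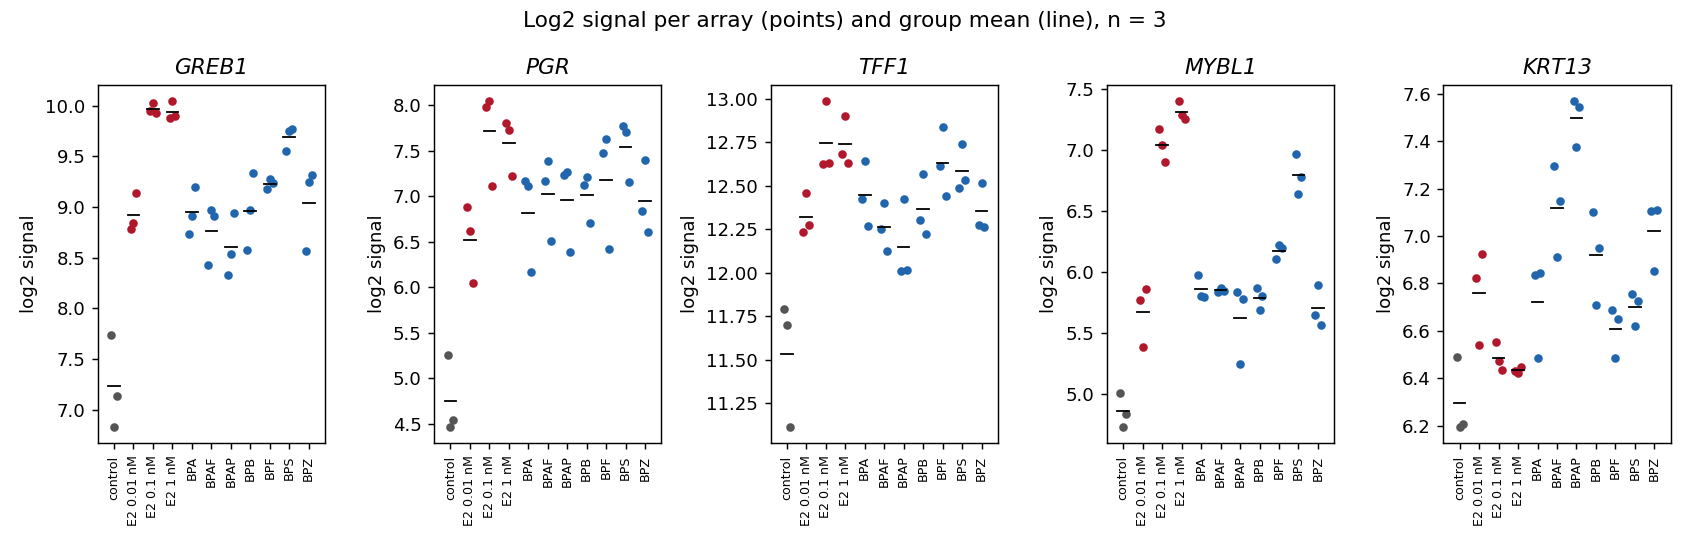
Log2 value of GREB1, PGR, TFF1, MYBL1 and KRT13 in each array (points) with the mean of each of the 11 groups (lines), 3 arrays each. KRT13 had its highest mean in BPAP, 7.50, against 6.30 in control and 6.43 with E2 at 1 nM, while MYBL1 went from 4.86 in control to 7.32 with E2 at 1 nM.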

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

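The fit over all probe sets was planned, and the split of its calls by kind of probe set was made after the data were seen. Probe sets with no listed gene carry signal outside the gene tests: in E2 at 1 nM against control 568 of 45168 passed (1.26%), 213 higher and 355 lower. Among probe sets with several gene symbols 54 of 1543 passed in the same comparison (3.50%), 33 higher and 21 lower, beside 922 of 23781 with a single symbol (3.88%).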

How the results depend on the processing

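Leaving out a replicate number in every group, cyclic loess (for BPZ against BPA) and the gene-by-gene array weights were chosen after the data were seen, the weights after both sets of counts were known. The trended and robust spread left every count of genes within 1.5 times, and cyclic loess left BPZ against BPA at 0. The planned default weights stopped before converging and are not given. The score differences from control and from E2 at 1 nM and the correlations with E2 kept their direction in every setting run, while the score of BPZ minus BPA turned with the median of members and that of BPAF minus BPA without BPA replicate 2 (-0.0046). A group left with 2 arrays is assumed to vary like the other groups. Values near the background means, up to 8.49, limit what dim genes can show. Unless a cause is named, the cause was not tested.

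With the replicate number as a block (pairing), the counts against control, in the order E2 at 0.01, 0.1 and 1 nM, BPA, BPAF, BPAP, BPB, BPF, BPS and BPZ, were 463, 2556, 2530, 1259, 1317, 1050, 1200, 1920, 2141 and 1448. Against E2 at 1 nM they were 101, 131, 329, 160, 173 and 129 for BPA, BPAF, BPAP, BPB, BPF and BPZ, for E2 at 0.1 against 0.01 nM 348, for BPAP against BPF 6 and for the F test 1413. Lists called were 11 for BPB against control and 4 for BPS against E2. Overlaps with E2 were 1157, 1170, 908, 1075, 1395, 1720 and 1201 for BPA, BPAF, BPAP, BPB, BPF, BPS and BPZ. Among named genes the block added 336 calls and ended 0, and among single lists it added 34 and ended 0. It changed no other call.

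With array weights the counts against control were 1877 for E2 at 0.1 nM, 1418 for BPA, 990 for BPAF, 664 for BPAP, 916 for BPB, 1481 for BPS and 1482 for BPZ. Against E2 they were 421, 179, 389, 299, 20, 3 and 222 for BPA, BPAF, BPAP, BPB, BPF, BPS and BPZ, for the E2 step 170, against BPA 109, 204, 223, 1, 9 and 3893 for BPAF, BPAP, BPB, BPF, BPS and BPZ, and for the F test 2950. Weights ran from 0.237 (BPZ replicate 2) to 4.64 (BPA replicate 1).

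With only the groups compared in the fit, which leaves fewer arrays to estimate the spread, the counts against control were 0, 396, 490, 17, 17, 16, 25, 23, 158 and 29 in the order above, against E2 2, 3, 10, 1, 2 and 3 for BPA, BPAF, BPAP, BPB, BPF and BPZ, for the E2 step 3, and 0 for BPAP against BPA, BPS against BPA and BPAP against BPF. With a fold of at least 1.5, a stricter rule, they were 35, 383, 394, 109, 128, 83, 110, 165, 289 and 117, and against E2 8, 21, 5 and 9 for BPA, BPAP, BPB and BPZ. BPB against E2 gave 20 with only the brighter genes, 19 quantile normalized again and 14 median centred. BPA against E2 gave 8 median centred. BPS against BPA gave 2 with all probe sets, 0 with the mean of probe sets and 2 median centred.

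With an estimated correlation 5, 5, 5, 5 and 4 lists were called for E2 at 1 nM, BPA, BPAF, BPAP and BPZ against control, and 2, 2, 2, 2, 2, 0 and 4 for BPA, BPAF, BPAP, BPB, BPF, BPS and BPZ against E2. With fry they were 5, 5, 5, 5 and 5, and 2, 1, 2, 2, 2, 0 and 3. With only the brighter genes BPS against E2 had 2.

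With the median of members the score difference from control was 1.00 and 0.95 for E2 at 0.1 and 1 nM, 0.67 for BPAF, 0.79 for BPF and 0.91 for BPS, from E2 -0.35, -0.28, -0.30, -0.31 and -0.38 for BPA, BPAF, BPAP, BPB and BPZ, for the E2 step 0.58, from BPA 0.075, 0.20, 0.31 and -0.030 for BPAF, BPF, BPS and BPZ, and for BPAP minus BPF -0.15. With the brighter members it was -0.28, -0.25 and -0.26 for BPAF, BPAP and BPB from E2. The correlation with E2 at 1 nM minus 0.01 nM was 0.493, 0.489, 0.432, 0.477, 0.444, 0.501 and 0.534, and with only the brighter genes 0.886, 0.856, 0.825 and 0.894 for BPAF, BPAP, BPF and BPS. At an adjusted p under 0.01 in both, overlaps were 122, 117, 86, 113, 197, 387 and 133, as fewer genes pass.

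Leaving out an array or a replicate number gave 5 to 133, 442 to 1212, 413 to 1210, 69 to 442, 87 to 455, 57 to 352, 81 to 396, 132 to 612, 298 to 942 and 113 to 511 genes against control, in the order above. Against E2 it gave 1 to 19, 1 to 15, 5 to 47, 1 to 20, 0 to 63, 0 to 2 and 1 to 10, for the E2 step 1 to 37, for BPAP against BPA 0 to 1, BPF against BPA 0 to 2, BPS against BPA 0 to 1, BPZ against BPA 0 to 1, BPAP against BPF 0 to 8 and the F test 71 to 394. Lists called against E2 were 2 to 8 for BPAP, 3 to 8 for BPA, 4 to 9 for BPB, 3 to 7 for BPF and 0 to 5 for BPS, and the correlation of BPF 0.759 to 0.813. Leaving out 1 array ended 593 calls of named genes and added 65. The direction of camera's test turned for 4 lists against E2: ribosomal proteins in BPZ when quantile normalized again (adjusted p 0.955), NRF2 in BPAF without BPAF replicate 2 (0.802, range over left-out arrays 0.000183 to 0.802), cholesterol in BPA without BPA replicate 3 (0.900, range 3.92e-06 to 0.900) and ribosome biogenesis in BPAP without replicate number 2 (0.938, range 0.000484 to 0.938).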

Other observations

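All comparisons between replicate numbers and with E2 at 0.01 nM, the tests of explanations and the counts over other splits of the arrays were chosen after the results were seen.

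Arrays with different replicate numbers differed in many genes whatever the treatment. Between replicate numbers 3 and 2, over all 11 groups, 3506 genes were higher and 3237 lower, 6743 in all, with 2926 between 2 and 1 and 3528 between 3 and 1. The following genes were chosen after their values were seen. Lower with number 3 were the surface glycoprotein genes CEACAM5 (-1.77) and MUC1 (-1.26) and the calcium-binding protein gene S100P (-1.16), and higher were TGFB2 (1.90), the matrix genes FN1 (1.63) and THBS1 (1.29), the caveolae gene CAV1 (1.46) and the Wnt inhibitor gene DKK1 (1.33), each with the same sign in 11 of 11 groups. Cholesterol biosynthesis and uptake was lower with number 3 (18 of 19 members, median -0.33, adjusted p = 6.94e-05 with an estimated correlation), and so was hypoxia and glycolysis (12 of 20 members, 3 higher, adjusted p = 0.014 with an estimated correlation).

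Set against the lowest E2 dose, 0.01 nM, the bisphenols had the following genes in the fit without a block. In BPAP only KRT13 passed (0.73, interval 0.50 to 0.97, adjusted p = 0.0239, 430 genes at an unadjusted p under 0.05). In BPS MYBL1 (1.12, adjusted p = 6.37e-05) and TIAM1, a Rac activator gene (0.55, adjusted p = 0.00418), were higher and MPZL2, an adhesion gene (-0.47, adjusted p = 0.0351), lower, with 882 genes at an unadjusted p under 0.05. For BPA, BPAF, BPB, BPF and BPZ limma called 0 genes, with 406, 403, 444, 1071 and 1055 at an unadjusted p under 0.05. With the replicate block, added after the data were seen, BPS had 93 genes, BPZ 14 and BPAP 6, KRT13 among them (adjusted p = 7.69e-06). BPAF then had AGR2 (0.53) and RET (0.55) higher and ARID5B (-0.36) lower, and BPA, BPB and BPF only EPAS1, lower by differences of -0.61, -0.55 and -0.55.

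The first pattern weighed is the set of 47 genes that differed between a bisphenol and E2 at 1 nM. A shift of the 3 E2 1 nM arrays against all others is argued against as the whole cause, since E2 at 0.1 nM differed from 1 nM in the direction of the bisphenols by a median of 0.13 (interquartile range 0.12) over these genes, below the median bisphenol difference of 0.53. A part stays open, as 42 of the 47 had the bisphenol direction there, in differences that share the E2 1 nM arrays. A weaker estrogen drive at the bisphenol doses stays open, as the direction of the genes cannot tell: 44 of the 47 differed in the same direction between E2 at 0.01 and 0.1 nM, but 1168 of the 1208 other genes called with E2 at 1 nM also lay on the side of a weaker effect at 0.01 nM.

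The second pattern is the higher KRT13 in BPAP. Against E2 at 1 nM KRT13 was called higher in 3 bisphenols, BPAP among them. The strength of the estrogen drive alone stays open, as no E2 dose matched BPAP in score. By score BPAP (7.41) lay between E2 at 0.01 nM (7.26) and 0.1 nM (7.64). KRT13 in BPAP exceeded E2 at 0.01 nM by 0.73 (interval 0.50 to 0.97) and E2 at 1 nM by 1.06 (0.82 to 1.30). Its lowest BPAP array, 7.38, lay above the highest array of any E2 dose, 6.92. A KRT13 peak at a strength between these doses stays open, as none was measured. BPA and BPF cannot decide: the smaller of the KRT13 differences of BPAP from BPA and from BPF was 0.77, but the score of BPAP differed from theirs by 0.05 (interval -0.04 to 0.15) and -0.03 (-0.12 to 0.06). GREB1 in BPAP differed by -0.63 (-1.06 to -0.20) from BPF and by -0.35 (-0.78 to 0.09) from BPA, so it does not place BPAP between them either. By GREB1 the BPAP arrays (8.33 to 8.94) overlapped those of E2 at 0.01 nM (8.79 to 9.14), where KRT13 was lower as well. KRT15 signal read by the KRT13 probe set is argued against as the whole cause, since KRT15 in BPAP differed from E2 at 0.01 nM by 0.12 (interval -0.10 to 0.34) where KRT13 differed by 0.73 (0.50 to 0.97), and 1 of 63 other keratin probe sets had an upper bound, 0.851, above the lower bound of KRT13. A part stays open, as KRT15 in BPAP lay 0.51 (0.30 to 0.73) above BPF.

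The third pattern is the difference between replicate numbers. A brightness-dependent difference between arrays is argued against as the whole cause, since 6509 genes still differed between numbers 3 and 2 after cyclic loess, 5628 of them in both fits. The background probe sets differed by a mean of -0.0089 (SD 0.0942). Independent experiments and arrays handled in batches by number cannot be told apart, as 33 of 33 arrays lay closest to their own number and the labels do not say what it marks, and no biological explanation was tested.

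With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. For each treatment against control 1 of the 10 splits gave as many genes as the real one, with 60, 1243, 1251, 321, 366, 253, 305, 603, 909 and 372 genes for E2 at 0.01, 0.1 and 1 nM, BPA, BPAF, BPAP, BPB, BPF, BPS and BPZ, and the highest other split gave 1 for BPA and BPAF and 0 for the rest. Against E2 at 1 nM it was 1 of 10 for BPA (13 genes), BPAF (19), BPAP (46), BPB (9), BPF (7) and BPZ (14), with the highest other at 1 for BPAP and BPB and 0 for the rest, and 10 of 10 for BPS (0, highest other 0). It was 1 of 10 for E2 at 0.1 against 0.01 nM (35, highest other 0), BPAP against BPA (1, highest other 0) and BPS against BPA (1, highest other 0), and 3 of 10 for BPAP against BPF (1, highest other 1). It was 10 of 10, with 0 genes in the real split, for E2 at 1 against 0.1 nM, BPAF against BPA and BPF against BPA (highest other 0), for BPB against BPA (highest other 1) and for BPZ against BPA. Among the splits that part all 3 pairs of equal numbers, as the real one does, the highest gave 1 gene for BPB against BPA and 0 for the rest. In BPZ against BPA a split with replicate numbers 1, 3 and 3 on a side called 4688 genes. That side held BPZ replicates 1 and 3 and BPA replicate 3, with array medians of 5.098, 5.069 and 5.065. The other side held BPZ replicate 2 and BPA replicates 1 and 2, with 4.956, 5.016 and 4.961. This split parts numbers 2 and 3 and also brighter from dimmer arrays, so it does not tell these apart. With the number as a block the real comparison had 0 genes. For the 355 genes of the F test 1 of 100 regroupings gave as many, the real one, and the highest other gave 5. Regrouped within replicate numbers, 1 of 100 gave as many as well, with the highest other at 1, and with the number as a block, 1413 genes, 1 of 100 with the highest other at 17. A share of 1 of 100, the smallest possible here, makes chance unlikely for the 11 groups as a whole. It does not bear on single comparisons.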
